A study of Mus musculus with 8 samples.

How the data were processed

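RNA was sequenced from mouse bone marrow dendritic cells that had been cultured overnight with 1 of 2 heat-inactivated bacteria of the genus Prevotella, P. melaninogenica (PM) or P. heparinolytica (PH). Per the labels' protocols, RNA was extracted with a column kit and polyadenylated RNA was made into strand-marking libraries. The series lists 8 libraries, 4 of PH and 4 of PM, which carry the sample ids 1, 3 and 4, and 2 of the 8 are labelled as run 2 (PM with id 1 and PH with id 3). The deposited table has 6 count columns, 1 for each treatment and sample id, and 2 of these columns match 2 libraries each by name. Whether these 2 columns hold 1 run or the sum of both is not given in the sources used here. Each column was used as 1 sample, which gave 3 PH and 3 PM samples, named here by their sample ids as replicates 1, 3 and 4. No columns of per-sample values were left out.

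The values are whole-number read counts per gene, deposited by the authors without normalization. Per the submitters' processing notes, Trimmomatic, STAR 2.5.3a, featureCounts 1.6.4 and the genome build GRCm38 were used. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The table names 55376 genes with exon coordinates. Of these names, 54510 were also in GENCODE mouse release 21, which has the same build, and 48709 of those had the same start and end. Coordinates in the text and exon overlaps between genes come from the deposited table, and gene types and GC content from GENCODE. Reads of near-identical family members (Ifit, Oas, Ifi20x, Gbp, Trim30 and H2 genes) could be split or lost in counting, so values of single members of these families are uncertain. With the strand setting unknown, values of genes that overlap another gene are uncertain too.

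Totals ranged from 11624367 counts in PH replicate 3 to 40233148 in PH replicate 4. Counts were tested with edgeR 4.0.16 (R 4.3.3) on TMM-scaled libraries, after filterByExpr with its minimum count of 10, which left 14382 genes. The quasi-likelihood test (glmQLFit with robust estimates, glmQLFTest) compared PM with PH with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are means ± SD of 3 samples, and log2 fold changes are PM over PH with the standard error (SE) derived from the test's F value. The labels do not say whether the sample ids are animals or cultures, so p-values measure the spread between these samples, which could be technical in part. On simulated counts with the genes' real means and library sizes, with 14216 genes tested, this fit recovered 60% of genes changed 1.5-fold, 92% of those changed 2-fold and 14% of those changed 1.25-fold, and 8.90% of its calls were false. With a block on simulated pairs and 14200 genes tested, these shares were 86%, 96% and 62%, and 9.47% of calls were false. Both false shares were above the nominal 5%. Each came from a single simulated dataset (13 of 146 and 18 of 190 calls), so they do not measure the rate expected over repeats. The first simulation also drew each sample independently, with no effect of the id shared by PH and PM. Its shares thus need not hold for the main fit if the ids pair the samples, as taken below.

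Sample ids were shared between the treatments, so a fit with the sample id as a replicate block was written down beforehand as an alternative. Whether the ids pair the samples was checked before the calls were compared, with the deviations of log2 CPM (prior count 2) from the treatment means over the 14382 genes. The correlation between PH and PM samples of the same id was 0.44 for id 1, 0.32 for id 3 and 0.24 for id 4, while pairs of different ids lay between -0.35 and 0.07. This contrast is built in for a part, since deviations from a treatment mean sum to 0. Positive values for the same ids thus push those of different ids down. With so few ids, the labelled matching could also rank highest by chance. With these limits the ids were taken to pair the samples, by a comparison planned before the data were examined and resting on the counts, not on the labels. The planned main fit stayed without the block, so its p-values do not use the pairing. The blocked value is given where it changes a call of edgeR or of camera with the preset correlation, or moves a count by over 1.5 times. No pair of columns agreed within sampling noise, since the chi-square per degree of freedom was at least 4.63 for each of the 15 pairs.

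The lists of genes, 22 of functions and 15 of cell type markers and RNA quality, were fixed before the data were examined. Each list with at least 3 tested genes was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The former takes its p-values from the residual degrees of freedom of the fit. With 3 samples per group these are few, so a list that did not pass by it says little. The function lists were inflammatory cytokines, Th17-polarising factors, regulatory genes, co-stimulatory and maturation genes, mature migratory dendritic cell genes, MHC class I and class II presentation, type I interferon response, interferon-gamma-inducible GTPases and targets, chemokines, NF-kB targets, pattern-recognition receptors, inflammasome, glycolysis and HIF targets, oxidative phosphorylation, cholesterol biosynthesis, cholesterol efflux and lipid genes, cell cycle, oxidative stress, unfolded protein response, complement, and lysosome. Genes named in the text followed a rule of the same time. It took the 12 genes higher and the 12 genes lower with PM that had the largest fold among those with an adjusted p under 0.05, at least 5 CPM in the higher treatment, no overlap between the samples of the treatments and a symbol other than a predicted gene's. It added up to 4 members of each list with the smallest p, and 12 genes named whatever their result (Il10, Il6, Il1b, Il23a, Il12b, Tnf, Tgfb1, Cd274, Cd80, Cd86, Cd40 and H2-Ab1). Outside the rule, Adgre1, Ch25h, Gm42418, Ifnb1, Ifng, Parp14 and Slfn5 were chosen after their values were seen. A gene that the rule could name is not reported here, and the counts include it.

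Alternatives were the replicate block, each sample left out in turn, RLE size factors, no filter beyond a count above 0, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, glmTreat against a 1.5-fold change and an adjusted p under 0.1. Added after the data were seen were the block in DESeq2, limma voom, and the block without each id in turn. Alternatives that treat the runs as separate libraries, which were planned, need counts per run and were not run.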

Results

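The dataset holds RNA-seq read counts of mouse bone marrow dendritic cells, antigen-presenting cells grown from bone marrow, that were stimulated overnight with heat-inactivated P. heparinolytica (PH) or P. melaninogenica (PM). The comparison asks how the transcriptional response of these cells differs between the 2 bacteria, in a study of the microbiome and PD-1/PD-L1 blockade in multiple myeloma. There were 3 PH and 3 PM samples and no untreated cells, so each difference below is between the bacteria and says nothing of either against rest. The total count was 24912460 in PH replicate 1, 11624367 in PH replicate 3 and 40233148 in PH replicate 4. It was 21192990 in PM replicate 1, 29565362 in PM replicate 3 and 38231719 in PM replicate 4. The shallowest sample, PH replicate 3, also had the highest level of Gm42418, a predicted gene, at 4013 CPM (counts scaled to a sample's total), against 867 to 1462 in the other 5 samples. Exons of Gm42418 overlap AY036118 and CT010467.1 over 87.3% of their length, so its reads may belong to those genes. PH replicate 3 thus differed from the other samples in depth and in this level, for a reason that was not tested.

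Cells given PM had lower levels of interferon-inducible genes, and a smaller group of genes was higher. Of 14382 genes tested, 337 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 101 higher and 236 lower with PM. The largest falls were those of Rtp4, a chaperone of receptor proteins (chromosome 16, 23520291 to 23614222, plus strand, GRCm38), at 18.8 ± 4.64 CPM with PH and 2.99 ± 0.483 CPM with PM (SD, n = 3), a log2 fold change of -2.68 ± 0.20 (SE) with adjusted p = 5.6e-04 by edgeR. Oasl2 (chromosome 5, 114896936 to 114912234) changed by -2.48 ± 0.19 and Ifit1 (chromosome 19, 34640871 to 34650009), an RNA-binding antiviral protein, by -2.39 ± 0.19. Cxcl9, a T cell-attracting chemokine, changed by -2.36 ± 0.21, and Irf7, a transcription factor of the interferon response, by -2.23 ± 0.17. Oas2 (-2.21), Iigp1 (-2.18), Oas3 (-2.01), Isg15 (-1.97), the chemokine Cxcl10 (-1.94), Ifi205 (-1.93) and the nucleic acid sensor Zbp1 (-1.81) completed the 12 genes with the largest falls. Each was lower with PM in 3 of 3 pairs, which the naming rule fixed, since it took only genes with no overlap between the treatments. With the sample id as a block, 2197 genes passed, 1007 higher and 1190 lower, and these included all 337. Without 1 sample the count was 240 (PH replicate 1), 208 (PH replicate 3), 142 (PH replicate 4), 417 (PM replicate 1), 174 (PM replicate 3) or 147 (PM replicate 4).

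The type I interferon list had 35 tested members, of which 30 fell with PM and 0 rose, with a median log2 fold change of -1.57. Adjusted over the list alone, 34 fell. Isg15, a ubiquitin-like modifier, was at 51.4 ± 4.16 CPM with PH and 13.2 ± 1.27 CPM with PM. The list of interferon-gamma-inducible GTPases and targets had 22 tested members, of which 16 fell (20 adjusted over the list alone) and 0 rose, with a median of -0.94. The GTPases Igtp (-1.26 ± 0.08 SE), Gbp2 (-1.0 ± 0.07) and Gbp3 (-1.0 ± 0.08), which act against pathogens inside cells, were among them. Both lists were lower by camera (adjusted p = 1.8e-46 and 6.5e-27), and both had adjusted p = 0.152 with an estimated correlation and 0.00276 by fry. The number of type I interferon members that passed was 24 to 32 when 1 sample was left out. Camera with the preset correlation passed 15 of the 37 lists, against 4 to 8 in the other splits of the 6 samples that parted all 3 id pairs, as the real one does, and 7 to 21 in the splits that parted 1 pair.

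**Figure D1:**
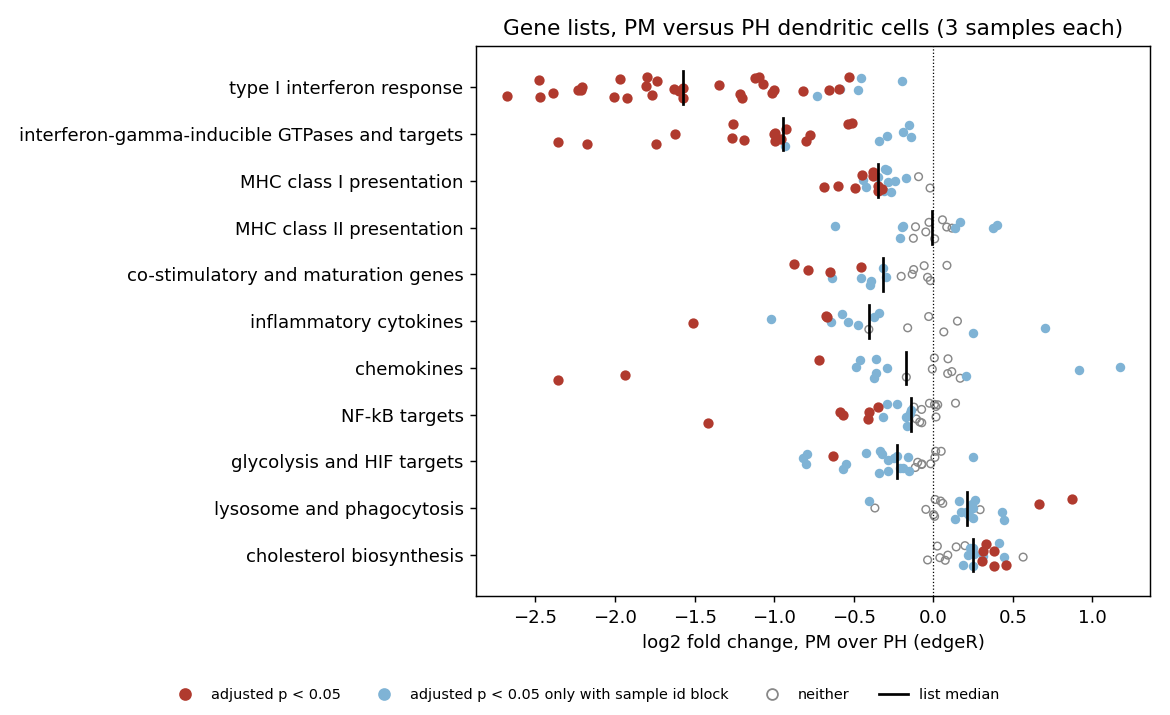
Log2 fold changes (PM over PH, 3 samples each) of the tested members of 11 gene lists, 1 point per gene, with a black bar at each list's median. Red points passed an adjusted p of 0.05 in the edgeR fit and blue points passed only with the sample id as a block. The type I interferon list has a median of -1.57 and the cholesterol biosynthesis list one of 0.25.

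Some genes of antigen presentation by MHC class I were lower with PM, while no gene of class II presentation passed. Of 22 class I members tested, 9 fell and 0 rose (19 fell adjusted over the list alone, 20 fell with the block), with a median log2 fold change of -0.34. Nlrc5, the transactivator of class I genes, changed by -0.69 ± 0.10 (SE), the non-classical class I genes H2-T22 and H2-M3 by -0.49 ± 0.06 and -0.45 ± 0.06, and the peptide transporter Tap1 by -0.60 ± 0.10. Camera gave adjusted p = 4.1e-16 for the list, and adjusted p = 0.204 with an estimated correlation, while fry gave 0.0115. Of 16 class II members, 0 passed (0 adjusted over the list alone), with 4 higher and 4 lower under the block. H2-Ab1, the class II beta chain, was at 817 ± 74.0 CPM with PH and 757 ± 29.7 with PM, a log2 fold change of -0.11 ± 0.08 that did not pass with either fit, at adjusted p = 0.646, or 0.135 with the block. The class I count was 5 without PH replicate 1, 4 without PH replicate 4 or PM replicate 4 and 3 without PH replicate 3 or PM replicate 3. Tap1 lost its call without PH replicate 3 (adjusted p = 0.0750), PH replicate 4 (0.0980) or PM replicate 3 (0.0502).

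Co-stimulatory and maturation genes fell in part. Of 17 tested, 4 fell and 0 rose (9 fell adjusted over the list alone, 10 fell with the block), and 2 fell without PM replicate 4. Cd40, the receptor for T cell help, was at 414 ± 44.6 CPM with PH and 263 ± 19.1 CPM with PM (log2 fold change -0.65 ± 0.09 SE, adjusted p = 0.00847 by edgeR). Slamf1, a receptor on activated immune cells, changed by -0.88 ± 0.08 and Tnfsf9, the ligand of 4-1BB, by -0.79 ± 0.09. The CD28 ligands Cd80 (-0.40 ± 0.09) and Cd86 (-0.39 ± 0.11) and the PD-1 ligand Cd274 (-0.28 ± 0.07, 776 ± 14.6 CPM with PH and 639 ± 35.8 with PM) were lower with PM in 3 of 3 pairs but did not pass without the block (adjusted p = 0.0687, 0.158 and 0.0914). With the block these 3 passed (adjusted p = 2.1e-07, 3.2e-07 and 4.4e-05 in edgeR). Camera gave adjusted p = 8.4e-08 for the list and 0.204 with an estimated correlation. Fry gave adjusted p = 0.0162, or 0.0444 with the block. Cd40 had adjusted p = 0.0551 without PM replicate 4.

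Among 17 inflammatory cytokine genes, 3 fell and 0 rose (6 fell and 1 rose adjusted over the list alone). Il23a, the p19 subunit of interleukin-23, was at 3.32 ± 0.191 CPM with PH and 1.14 ± 0.140 with PM (log2 fold change -1.51 ± 0.18 SE, adjusted p = 0.00394 by edgeR). Il6 changed by -0.67 ± 0.12 and Ebi3, a subunit of interleukin-27 and interleukin-35, by -0.67 ± 0.08. Exons of Ebi3 overlap another gene over 23.4% of their length. Il10, the anti-inflammatory cytokine of the regulatory list, was also lower, at 71.0 ± 11.1 CPM with PH and 45.7 ± 4.06 with PM (-0.63 ± 0.12, adjusted p = 0.0268 by edgeR). Il12b (-0.58 ± 0.19), Il1b (-0.53 ± 0.23) and Tnf (-0.34 ± 0.25) did not pass (adjusted p = 0.221, 0.360 and 0.646), nor did Tgfb1 (0.29 ± 0.10, adjusted p = 0.247). Each of these 4 passed with the block, the first 3 lower and Tgfb1 higher with PM in 3 of 3 pairs. The blocked counts were 10 cytokine genes lower and 2 higher. Il6 lost its call without PM replicate 3 or 4 (adjusted p = 0.110 and 0.122) and Il10 without any sample but PH replicate 1 (adjusted p 0.0579 to 0.122).

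**Figure D2:**
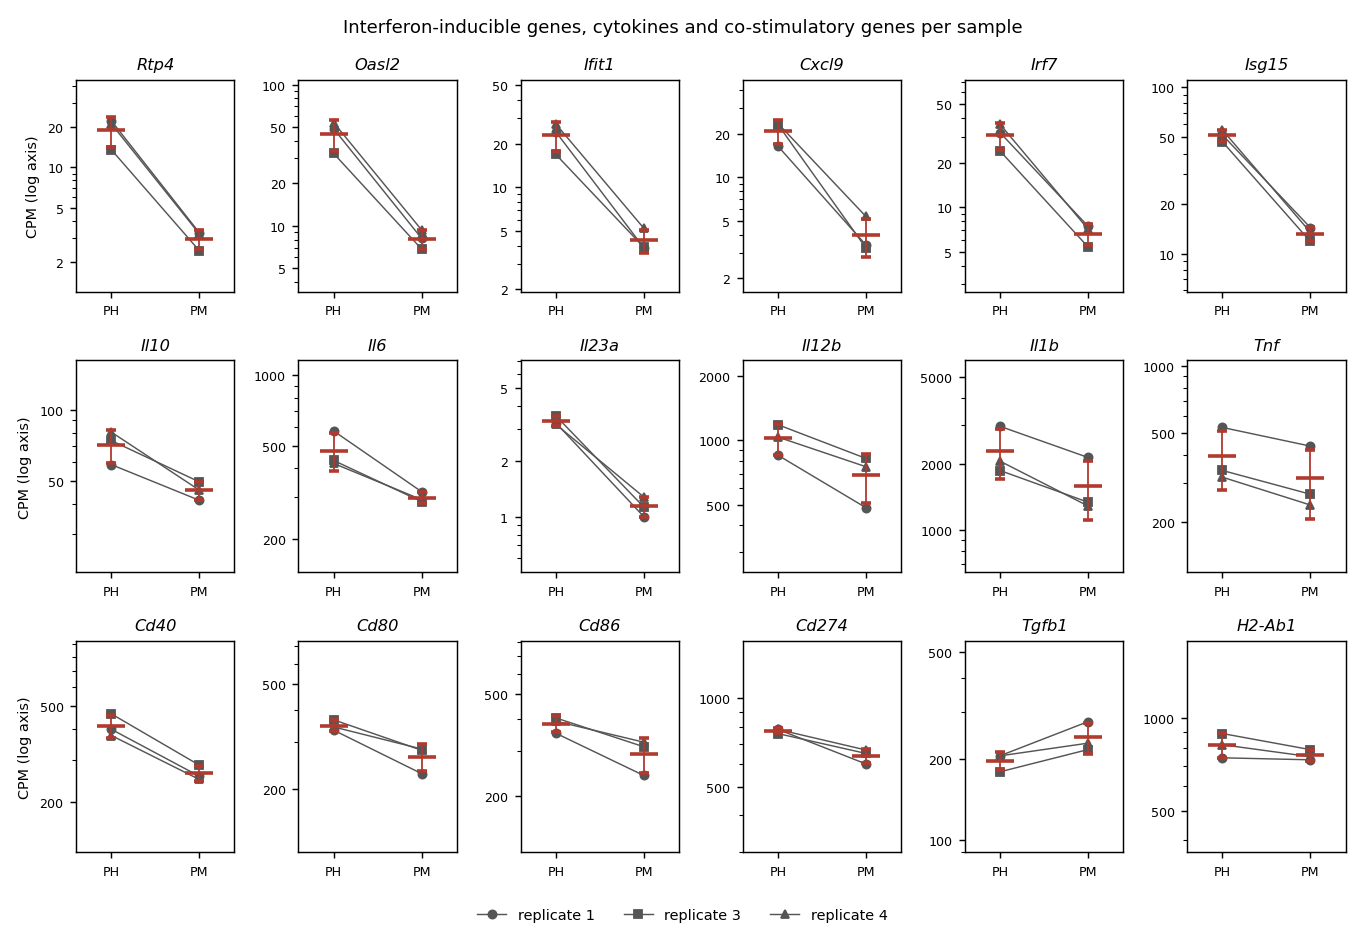
CPM (log axis) of 18 genes in each PH and PM sample, with lines joining samples of the same id and red bars at the mean ± SD of 3 samples. Rtp4 falls from 18.8 CPM to 2.99 CPM, and H2-Ab1 lies at 817 CPM and 757 CPM.

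Of 10 Th17-polarising factors, 3 fell and 0 rose (5 fell and 1 rose adjusted over the list alone, 7 lower and 1 higher with the block), and 1 without PM replicate 3. These were the cytokine genes Il23a and Il6 and Tnfsf15, a TNF family ligand (-0.60 ± 0.11 SE). Of 19 chemokine genes, 3 fell and 0 rose (5 lower and 2 higher adjusted over the list alone, 9 lower and 3 higher with the block). Without PH replicate 1, 3 chemokine genes were lower and 2 higher. Ccl5, which attracts T cells and monocytes, changed by -0.72 ± 0.08 next to the interferon-inducible Cxcl9 and Cxcl10. Of 24 NF-kB targets, 6 fell and 0 rose (8 adjusted over the list alone, 13 with the block). They included the acute-phase protein gene Saa3, at 4364 ± 473 CPM with PH and 1636 ± 538 with PM, and the NF-kB inhibitors Tnfaip3 (-0.56 ± 0.07) and Nfkbia (-0.40 ± 0.07). Camera gave adjusted p = 1.5e-04 for the Th17 factors, 0.0264 for chemokines, 1.5e-06 for NF-kB targets and 0.00156 for cytokines. With an estimated correlation the adjusted p was 0.152, 0.582, 0.204 and 0.204. Fry gave these lists, in the same order, adjusted p = 0.00274, 0.0598, 0.0217 and 0.0443, or 0.00967 for each with the block. The chemokine list lost its camera call without PH replicate 1 or PM replicate 3 or 4 (adjusted p 0.0811 to 0.247), and in the blocked fit without id 1 or 3 (0.0665 and 0.0699). The NF-kB count was 3 without PH replicate 3, 2 without PH replicate 1, PH replicate 4 or PM replicate 3 and 1 without PM replicate 4. Saa3 had adjusted p = 0.0522 without PM replicate 4, 0.155 with no low-count filter and 0.0622 in the blocked fit without id 3. Tnfsf15 had adjusted p 0.0564 to 0.110 without PH replicate 1, 3 or 4 or PM replicate 3, and Nfkbia 0.0594 to 0.126 without any sample but PM replicate 1.

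The genes with the largest rises with PM came from several functions. Emp1, an epithelial membrane protein gene (chromosome 6, 135362545 to 135383173, plus strand), was at 19.2 ± 4.00 CPM with PH and 50.7 ± 2.56 CPM with PM, a log2 fold change of 1.38 ± 0.13 (SE, adjusted p = 0.00128 by edgeR). Cd28, known as a co-stimulatory receptor of T cells, changed by 1.20 ± 0.11, Dio2, a thyroid hormone deiodinase, by 1.12 ± 0.15, and Clec7a, the beta-glucan receptor dectin-1, by 1.11 ± 0.16 from 159 ± 34.2 to 343 ± 52.1 CPM. Stra6l (1.01), the phosphodiesterase Pde7b (1.01), Aoc1 (0.99), Lhfpl2 (0.98), Syngr1 (0.96), the decoy TNF receptor Tnfrsf26 (0.96), the endolysosomal channel Mcoln3 (0.95) and Dok7 (0.89) completed the 12. Each was higher in 3 of 3 pairs, which the naming rule fixed here too. GENCODE lists Clec7a as a polymorphic pseudogene. Clec7a lost its call without PH replicate 4 (adjusted p = 0.0601), as did Stra6l (0.0996), Syngr1 (0.0591) and Dok7 (0.191), and Stra6l and Syngr1 lost theirs without PM replicate 4 (0.0750 and 0.0642). Pde7b and Mcoln3 lost theirs without PH replicate 1 or 3 or PM replicate 3 or 4, and Dok7 without PH replicate 3 or PM replicate 3 or 4 as well (adjusted p 0.0695 to 0.125).

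Some cholesterol biosynthesis genes were higher with PM. Of 23 tested, 6 rose and 0 fell (13 adjusted over the list alone, 15 with the block), with a median log2 fold change of 0.25. Cyp51, lanosterol demethylase, was at 107 ± 1.49 CPM with PH and 139 ± 7.67 with PM (log2 fold change 0.38 ± 0.06 SE), Sqle, squalene epoxidase, changed by 0.38 ± 0.07 and Mvd, mevalonate decarboxylase, by 0.46 ± 0.09. Of 24 lysosome and phagocytosis genes, 2 rose and 0 fell (5 higher and 1 lower adjusted over the list alone, 14 higher and 1 lower with the block), with a median of 0.21 that was 0.138 without PH replicate 3 and 0.0853 without PM replicate 1. These 2 were Atp6v0d2, a proton pump subunit (0.66 ± 0.08), and the protease gene Ctsk (0.88 ± 0.17). Camera gave adjusted p = 1.1e-09 and 2.9e-04 for the 2 lists, and 0.204 and 0.597 with an estimated correlation. Fry gave adjusted p = 0.0162 and 0.157, or 0.0666 and 0.0288 with the block. Without 1 sample, 0 (PH replicate 1, PH replicate 4, PM replicate 4), 1 (PH replicate 3, PM replicate 3) or 6 (PM replicate 1) cholesterol genes passed, and 1 lysosomal gene without any sample but PH replicate 1, Ctsk keeping its call only without PH replicate 1 (adjusted p up to 0.153) and having adjusted p = 0.168 with no low-count filter.

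**Figure D3:**
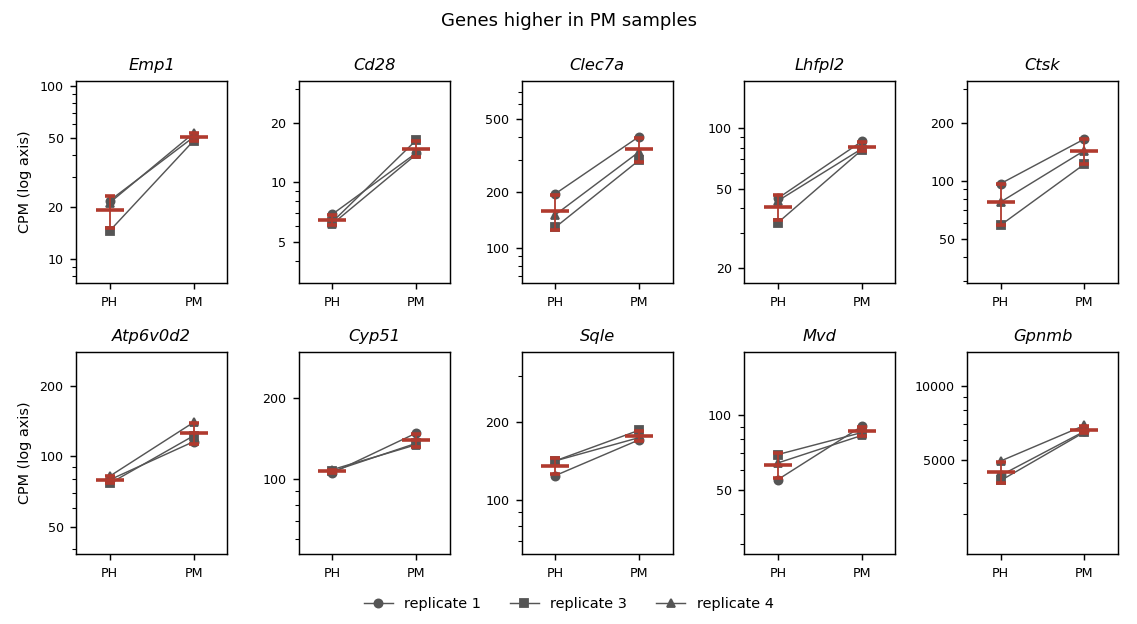
CPM (log axis) of 10 genes higher with PM in each PH and PM sample, with lines joining samples of the same id and red bars at the mean ± SD of 3 samples. Emp1 rises from 19.2 CPM to 50.7 CPM, and Cyp51 from 107 CPM to 139 CPM.

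Glycolysis and HIF target genes showed the largest gap between the fits. Of 27 tested, 1 fell (3 adjusted over the list alone), Ndrg1 at -0.63 ± 0.09 (SE), while with the block 18 fell and 1 rose, among them Pfkfb3, an activator of glycolysis (-0.34), and the mitophagy receptor Bnip3 (-0.81, a gene whose exons overlap another gene over 27.2% of their length). Of 20 mature migratory dendritic cell genes, 3 fell (6 adjusted over the list alone, 10 with the block), among them Marcksl1 (-0.55 ± 0.10) and Cd200 (-0.36 ± 0.07). Of 16 inflammasome genes, 1 fell (3 adjusted over the list alone, 5 lower and 1 higher with the block), Casp4, the receptor for cytosolic lipopolysaccharide (-0.49 ± 0.06). Camera gave adjusted p = 3.4e-04, 0.00127 and 0.0321 for these 3 lists and 0.723 for each with an estimated correlation. By fry none of the 3 passed (adjusted p = 0.502, 0.432 and 0.431), and with the block the values were 0.0827, 0.0661 and 0.00967. These camera calls were lost without some samples, for glycolysis without PM replicate 3 (0.0749), for the migratory genes without PH replicate 3 or PM replicate 1 (0.0551 and 0.0958) and for the inflammasome without PH replicate 1 or PM replicate 3 or 4 (0.113 to 0.273) or with a filter of 1 CPM (0.0679). The migratory count was 1 without PH replicate 1 and 0 without PH replicate 3 or 4 or PM replicate 3 or 4, and the inflammasome count was 3 without PM replicate 1. Ndrg1 had adjusted p = 0.06 without PH replicate 4. Marcksl1 had 0.0512 to 0.141 without any sample but PH replicate 1 and PM replicate 1, and Cd200 had 0.0904 to 0.199 without any sample but PM replicate 1.

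Of 138 markers of cell types and of RNA quality, 5 passed, and 39 (16 higher and 23 lower with PM) did with the block, 28.3% of them against 15.3% of all genes. Of 17 neutrophil markers, 1 fell (5 lower and 1 higher with the block), the G-CSF receptor gene Csf3r (-0.96 ± 0.09 SE, 16.3 ± 0.837 CPM with PH). Of 4 NK cell markers 1 fell (2 with the block), the cytotoxic protease gene Gzmb (-0.85 ± 0.09), of 9 stromal markers 1 fell (2 with the block), Pdgfrb (-0.70 ± 0.10), and of 12 T cell markers 1 rose, Cd28. Of 8 macrophage markers 1 rose (3 higher and 1 lower with the block). Of 12 conventional dendritic cell markers 0 passed (5 higher and 1 lower with the block), of 7 plasmacytoid markers 0 (1 lower with the block) and of 10 monocyte markers 0 (5 lower with the block, such as Ly6c2). Camera was past the threshold for the monocyte and NK cell lists (adjusted p = 0.0246 and 0.0110, and 0.723 and 0.582 with an estimated correlation). Fry gave adjusted p = 0.502 and 0.0675, or 0.0233 and 0.0473 with the block. The monocyte call of camera was lost without PH replicate 1 (0.315) or PM replicate 3 (0.149). The NK cell call of camera was lost without PH replicate 3 (0.0650), without PM replicate 1 (0.201) or in the blocked fit without id 1 (0.117). Camera gave adjusted p = 0.143 for the megakaryocyte list and 0.0230, higher with PM, with the block (0.435 with the block and an estimated correlation). Some lists that did not pass in the main fit passed when samples were left out. Without PH replicate 1 these were the megakaryocyte (0.00365, higher with PM), stromal (0.0208, lower) and B cell (0.0345, higher) lists. The neutrophil list passed without PH replicate 3 (0.0248, lower) or PM replicate 1 (0.0150, lower), and in the blocked fit without id 1 the neutrophil (0.0320) and stromal (0.0191) lists were lower. With all samples and an estimated correlation the adjusted p was 0.900 for megakaryocyte, 0.932 for stromal, 0.948 for B cell and 0.948 for neutrophil markers. No member passed among 10 mast cell and basophil, 8 eosinophil, 9 B cell, 3 erythroid and 7 megakaryocyte markers, 7 mitochondrial transcripts or 15 immediate early and heat shock genes, while with the block 1 eosinophil marker was higher and 1 lower, 1 B cell marker and 1 megakaryocyte marker were higher, and 3 early genes were higher and 5 lower. Adjusted over each list alone, 1 dendritic cell marker was higher and 1 lower, 3 macrophage markers and 1 T cell marker were higher, 3 monocyte, 2 NK cell, 1 plasmacytoid, 1 neutrophil and 1 stromal marker were lower, 3 early genes were higher and 3 lower, and 0 members of the other 6 lists passed. Without 1 sample, 0 macrophage markers passed (PH replicate 3, PH replicate 4 or PM replicate 4), 2 NK cell markers fell (PH replicate 1), and 2 monocyte markers and 1 early gene fell (PM replicate 1). Pdgfrb had adjusted p = 0.0624 without PH replicate 4.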

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

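The blocks within DESeq2, without each id in turn and combined with the other list tests, and limma voom were added after the data were seen. Direction held for each gene that passed: none of the 337 calls changed sign in any fit. The count of 337 genes (101 higher, 236 lower with PM) and 92 list members stayed within 1.5 times under RLE size factors (339), 1 CPM in 3 samples (335) and limma voom (357). It moved under the replicate block (2197 genes, 1007 higher and 1190 lower, 259 members), where the spread between pairs leaves the error. It moved also without a filter (846, 349 and 497, 154 members), with DESeq2 (577, 202 and 375), at an adjusted p under 0.1 (567, 205 and 362) and with glmTreat, which tests against 1.5-fold (44, 3 and 41, 29 members). DESeq2 with a replicate block gave 1193 (462 and 731, 222 members). The replicate block without id 1 gave 2145 (868 and 1277, 265 members), without id 3 1580 (644 and 936, 215 members) and without id 4 1529 (696 and 833, 230 members). Except where named, the cause was not tested. Leaving out 1 sample gave 142 to 417 genes, 26 to 111 higher, 107 to 306 lower, and 54 to 101 members. Lists past the threshold numbered 15, then 17 with the block, 11 to 16 without 1 sample, 8 with fry (13 with the block, which ended the fry call of cholesterol biosynthesis, adjusted p 0.0162 to 0.0666), and 0 with an estimated correlation, with or without the replicate block. The correlation itself does not account for all of that loss. For Th17-polarising factors it was estimated at -0.080, below the preset 0.01, yet camera's p rose from 2.7e-05 to 0.0119. A list that did not pass there is thus not shown to owe its call to co-regulation.

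Medians near 0 changed sign when 1 sample was left out. Their ranges were -0.0989 to 0.0594 for MHC class II, -0.0137 to 0.175 for pattern-recognition receptors, -0.0242 to 0.0579 for oxidative phosphorylation, -0.0615 to 0.0997 for cholesterol efflux and lipid genes, -0.0921 to 0.0661 for oxidative stress and -0.0703 to 0.0541 for the unfolded protein response. In the block without id 1 the oxidative phosphorylation and unfolded protein medians were -0.00915 and -0.0493, and without id 4 that of oxidative stress was 0.0243. The cause was not tested. Ch25h, which did not pass, ranged from -0.72 to 0.11 when 1 sample was left out, Adgre1 from -0.251 to 0.142, Eomes from -0.249 to 0.335 and Klre1 from -0.278 to 0.216, none of which passed. Eomes was -0.0707 with DESeq2 and a replicate block, -0.0128 with limma voom, and -0.0431 and -0.258 in the block without id 3 and without id 4, and Klre1 was 0.0672 in the block without id 3. Of 64 named genes that passed, 37 also passed in each fit that left out 1 sample. Among named genes, the block took 12 past the threshold and ended no call.

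The 3 samples per group limit what a split of the samples can show, since 10 splits cannot give a share under 0.05. Of the 10 splits, 1, the real one, gave as many as 337 genes, and the highest other gave 0, while list members were 92 against 0. With labels exchanged within pairs, 1 of 4 splits, the real one, gave as many as 2197 genes, and the highest other gave 0. For lists, 5 of 10 splits gave 15 or more, with 21 the highest other. The splits with more than 15 lists each parted 1 pair and kept the other ids together, whereas those that parted 3 pairs, like the real one, gave 4 to 8. Alternatives planned on the runs as separate libraries were not run: run 1 only, 8 libraries with or without a run term, in edgeR, DESeq2 or limma, and the agreement of repeat runs. At these depths 14382 genes were tested, against 27765 without a filter, so genes with few counts are outside the counts given.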

Other observations

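All tests on gene families and the interferon, Ch25h and cell type tests below were chosen after the result was seen, as were the genes Parp14, Slfn5, Ifnb1, Ifng, Ch25h and Adgre1, whereas the matched lists were planned. Among 392 families of symbols with a common stem and at least 5 tested members, 8 held more genes lower with PM than expected (Fisher's exact test, Benjamini-Hochberg), and 0 held more genes higher. Beside the Ifi, Gbp, Ifit, Oas and Irf genes, these were Parp (4 of 12, adjusted p = 0.00270), Trim (6 of 45, 0.00645) and Slfn, the schlafen family (3 of 9, 0.0204). The 6 Trim genes include Trim30a, Trim30b, Trim30c and Trim30d. Reads of such copies may be shared, as for Ifit3 and Ifit3b or Oas1a and Oas1g, while Fisher's test counts each member as independent. With the block Parp and Irf were not past the threshold, Psme (4 of 5, 0.0161), Dock and Traf (each 5 of 10, 0.0385) were, and the others remained, Ifit at 0.0161, Trim at 0.0489 and Slfn at 0.00251. Parp14 had a log2 fold change of -1.10 ± 0.08 (SE) and Slfn5 one of -1.16 ± 0.10, at 124 CPM with PH and 55.4 CPM with PM.

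Pattern-recognition receptors moved in both directions. Of 26 tested, Clec7a rose, while the scavenger receptor gene Marco (-0.74 ± 0.10 SE) and the peptidoglycan sensor gene Nod1 (-0.59 ± 0.12) fell, and 9 were higher and 3 lower with the block (1 higher and 2 lower adjusted over the list alone). Of 26 regulatory genes, Cd200r1 (0.65 ± 0.10) and Gpnmb (0.58 ± 0.09) were the 2 higher and 3 were lower, with 5 higher and 12 lower under the block (4 and 7 adjusted over the list alone). Of 10 complement genes, 1 fell (1 adjusted over the list alone), Cfb (-1.27 ± 0.19), whose exons overlap Gm20547 over 81.6% of their length, with 6 lower and 1 higher under the block. Camera gave the complement list adjusted p = 0.0840, and with the block 0.00667 (0.487 with the block and an estimated correlation). Complement also passed, lower with PM, without PH replicate 3 (0.0216) or PM replicate 1 (0.00500), with no filter (0.0169) and with a filter of 1 CPM (0.0441). The cell cycle list had camera adjusted p = 0.0840, and was lower without PH replicate 1 (5.7e-04) or PM replicate 4 (0.00431), while the oxidative stress list was lower without PM replicate 1 (0.0150). With all samples and an estimated correlation the adjusted p was 0.940 for cell cycle and 0.948 for oxidative stress. The cell cycle list had 1 of 28 lower, Mki67 (-0.38 ± 0.06), and 9 lower and 1 higher with the block, and the unfolded protein list 1 of 20 higher, Herpud1 (0.35 ± 0.06), and 4 higher and 4 lower with the block. No member passed among 30 oxidative phosphorylation genes (1 higher with the block), 20 lipid efflux genes (7 higher and 4 lower) and 20 oxidative stress genes (2 higher and 5 lower). Adjusted over the list alone, the cell cycle list had 1 higher and 4 lower, the unfolded protein list 4 higher and 2 lower, and the other 3 lists 0. The regulatory count was 3 without PH replicate 1, 2 without PH replicate 3, PH replicate 4 or PM replicate 3 and 1 without PM replicate 4, and the receptor count was 1 without PH replicate 4. Without PM replicate 1, 2 complement genes, 1 lipid efflux gene and 1 oxidative stress gene were lower. With 1 sample left out, each of these named genes but Marco lost its call in some fits, Cd200r1 without PH or PM replicate 4 (adjusted p = 0.0617 and 0.0618), Cfb likewise (0.0557 and 0.0632), Gpnmb in 4 of 6 fits (0.0586 to 0.102), Nod1 in 5 (0.103 to 0.170), Mki67 in 4 (0.0700 to 0.118), Herpud1 in 4 (0.0842 to 0.131) and Clec7a in 1 (0.0601).

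The fall of interferon-inducible genes with PM held outside gene families with near-identical copies, where reads shared between paralogs cannot be the whole cause: the 19 members outside these families had a median log2 fold change of -1.10 (SE of their mean 0.16). A loss of plasmacytoid cells, a major source of type I interferon, cannot be told apart from a lower signal, since the median of their 7 markers was -0.10 but only 3 reached 5 CPM. A weaker stimulation overall may also contribute, as the 59 NF-kB, cytokine and chemokine genes outside the interferon lists had a median of -0.17, a smaller fall that no untreated cells can calibrate. Counts of Ifnb1 were 0 to 4 per sample, too few to compare, whereas Ifng, at 3 to 38 counts, was lower with PM in 3 of 3 pairs (0.852 ± 0.245 CPM with PH and 0.313 ± 0.160 with PM, SD, adjusted p = 0.182, or 0.00753 with the block), as were the NK cell genes Gzmb and Gzma (adjusted p = 0.0522 for Gzma, or 5.3e-06 with the block) but not the other 2 NK markers, Eomes (log2 fold change 0.06 ± 0.35 SE) and Klre1 (-0.02 ± 0.39), both with means under 2 CPM. Exons of Ifng overlap Gm49751 over 20.6% of their length. Less interferon-gamma, or fewer cells that make it, stays open, as do other effects of the bacteria.

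The median of the cholesterol biosynthesis list, of whose 23 genes 6 passed, was not matched by random lists of the same gene length, GC content and expression, of which a share of 0.0001, the smallest that 10000 lists can give, had as high a median in either fit. This speaks to length, GC content and expression only, since random genes are not co-regulated. Camera with an estimated correlation gave adjusted p = 0.204 (0.487 with the block), but its few degrees of freedom keep it from deciding on co-regulation. A candidate explanation is less 25-hydroxycholesterol, which represses these genes and is made by the interferon-inducible enzyme Ch25h. Ch25h had a log2 fold change of -0.32 ± 0.36 (SE) and was lower with PM in 3 of 3 pairs, with -0.263 ± 0.125 under the block, over 2 SE below 0 but at adjusted p = 0.177, and 0.11 without PH replicate 1, which leaves this open, as it does other effects of the bacteria.

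The median of the lysosome list, of whose 24 genes 2 passed, was likewise not matched by random lists (share 0.0001 in either fit), with the same limit. Camera with an estimated correlation gave adjusted p = 0.597 (0.487 with the block), which cannot decide on co-regulation here either. A lower share of dendritic cells would raise the markers of each other cell type alike. Of the monocyte and neutrophil markers past the threshold with the block, 10 were lower and 1 higher with PM (exact sign test, two-sided p = 0.0117). That test counts markers as independent, which markers of the same cell type need not be. In the block without id 1, monocyte markers were 6 lower and 1 higher, and neutrophil markers 5 lower and 2 higher. Dendritic cell markers were 5 higher and 1 lower with the block, but 2 higher and 3 lower without id 1. A lower share of dendritic cells therefore stays open. More macrophages may contribute, since 1 of 8 macrophage markers passed and was higher, with 5 of 8 having a positive log2 fold change. The abundant marker Adgre1, at 504 CPM with PH, had a log2 fold change of -0.05 ± 0.18, so this stays open, as do other effects of the bacteria.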
